A study of Mus musculus with 8 samples.

How the data were processed

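RNA of embryonic stem cells was extracted with Trizol, and 500 ng per sample went into QuantSeq 3' mRNA-Seq FWD libraries, which are primed at the poly(A) tail and read transcript ends. The deposited values are raw counts of reads per Ensembl gene for 8 libraries, with no normalization. The processing notes in the labels name Trim Galore for read trimming and the GRCm38 genome build, without versions. The aligner, the counting program, the annotation release, the strand setting and any use of molecular identifiers are not given in the sources used here. The values were checked to be whole numbers, and each of the 8 columns was mapped to its sample by group and replicate number, with 0 columns left unmapped. The table held 55421 gene identifiers, of which 55154 were matched to a symbol and position in GENCODE M21 for GRCm38, and 267 were not. The 2 libraries of each group differed by more than counting noise (chi-square per degree of freedom of 30.5 in siTfap4, 19.4 in siWiz, 17.7 in siZic2 and 37.7 in siNeg), so they were not repeat reads of 1 library. PCR reads without known molecular identifiers are not independent molecules, so the counting intervals and floors given for low counts cover counting error only.

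Genes were filtered with filterByExpr, which left 14647, scaled with TMM factors and fitted with the quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, with 1 mean per group, all 8 libraries in 1 fit and no block. The common dispersion was 0.0495, a biological coefficient of variation of 22.2%, with 4 residual degrees of freedom and 9.7 prior degrees of freedom. The 6 comparisons were each siPOOL against siNeg and each pair of siPOOLs. P-values were adjusted by Benjamini-Hochberg over the genes tested in each comparison, with a threshold of 0.05, and "rose", "fell", "higher" or "lower" as a call means passing it. Levels are CPM, counts scaled to a common library size by TMM, given as mean ± SD of 2 libraries. The SE of a log2 fold change was derived from its quasi-likelihood F statistic. Log2 CPM values for the principal components used a prior count of 2. For a gene with 0 counts in a group, a floor of 3 counts over the group was used, and for 1 to 3 counts the ratio was given with an exact binomial counting interval at the 95% level.

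The named genes, gene lists, tests and alternatives were fixed before the data were examined. The naming rule took the 3 targeted genes in every comparison. For each siPOOL against siNeg it took the 8 called genes with the largest log2 fold change in each direction, with a mean of at least 5 CPM and no overlap between the CPM of the libraries compared. For each list it took up to 4 called members with the smallest p, or up to 2 members with the smallest p, given as values, if none was called. For genes called the same way in 2 or 3 comparisons it took the 5 with the smallest largest p, and for pairs of siPOOLs up to 5 genes with the smallest p. Gene models without a name and pseudogenes counted toward the rule and were mostly summarised as a number. Exceptions are marked where they occur.

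The 31 lists covered general and naive pluripotency factors, formative and primed, 2C-like, trophectoderm, primitive endoderm, mesoderm, neural and fibroblast markers, germline and imprinted genes, the protocadherin beta cluster, and epithelial and EMT genes. They also covered targets of Wnt, Nodal and BMP, ERK, and LIF and STAT3 signalling, p53 targets, interferon-stimulated, integrated stress response, cholesterol synthesis, glycolysis and hypoxia, DNA replication, mitosis, ribosome biogenesis and ribosomal protein genes, mitochondrially encoded mRNAs, RNA interference machinery, described targets of the deleted microRNAs, and relatives and partners of the targeted factors. The 30 lists with at least 5 tested members were tested with camera (limma 3.58.1) at the preset correlation of 0.01, adjusted over 30 lists and 3 comparisons with siNeg. Camera asks whether a list moved differently from the other genes. Beside it, camera with an estimated correlation and fry were run. fry asks whether the members moved on balance one way, without a comparison with other genes. The lists share some members, so their results are not independent.

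The alternatives were size factors of the RLE method, library totals alone, no filter beyond 1 count, a mean of at least 5 CPM, a fit of the compared groups alone, the replicate number as a block, each library left out in turn, a 1.5-fold minimum, and DESeq2 1.42.0. With a library left out, the single library of its group was assumed to vary like the other groups. Further alternatives were chosen after seeing the data: both siTfap4 libraries left out, with and without the replicate block, both siWiz libraries left out, a covariate for the difference between the 2 siWiz libraries, protein-coding genes alone, these genes corrected for GC content of the last 300 bases and for length, and every library thinned to the smallest total. The form of the GC correction was revised after its first result was seen.

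The pipeline was tested on simulated data with the depth and spread of these libraries, in 5 runs with 200 changed genes. It recovered 0.896% of 1.5-fold, 17.0% of 2-fold and 75.2% of 4-fold changes in the siTfap4 comparison, and called on average 4.4 unchanged genes per run. A list of 20 doubled genes had an unadjusted camera p under 0.05, at the preset correlation, in 5 of 5 runs. That list was tested alone and the simulated genes varied independently, so this does not test the adjusted list calls. The GC correction was tested on simulated data with such a trend and no other change, where it brought 283 calls to 0. With the trend and 200 genes changed 4-fold, it recovered 88.4% of those tested, as without it, and brought 498 other calls to 6. The covariate was tested on simulated data with a random axis, put into siTfap4 and more weakly between the replicate numbers of every group. With the siWiz libraries left out it brought 1745 calls to 0. With 200 genes also changed 4-fold, it recovered 4.15% of those tested against 79.8% without it, so its calls were not used as evidence. In the fit of all 8 libraries the covariate recovered 59.9% against 79.2%, with 101 other calls against 1476. The simulations with 4-fold changes were added after the results were seen. Correlations between comparisons were set against 100 simulations of unchanged groups. Shared sequence was searched with words of 36 bases, in steps of 4, over the last 400 bases of 12482 transcripts, of which 291 shared most of their words with another gene, and 11 of 181 named genes did. Of 187 named genes, 1 overlapped another gene's exon at its end on the same strand and 12 on the opposite strand.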

Results

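The study measured polyadenylated RNA in mouse embryonic stem cells of 129/Ola background that lack the microRNA cluster from Mir290a to Mir295, which is abundant in wild-type cells of this kind. The cells were grown with serum and the cytokine LIF, which maintains self-renewal. They were transfected with a siPOOL, a mixture of small interfering RNAs against 1 transcript, at 5 nM, and harvested 36 h later. The 3 targeted transcripts encode DNA-binding factors: Tfap4 is a basic helix-loop-helix protein that binds E-boxes, Wiz is a zinc finger partner of the histone H3 lysine methyltransferases Ehmt1 and Ehmt2, and Zic2 is a zinc finger factor of the primed pluripotent state. A negative control siPOOL made the fourth group. Each of the 4 groups (siTfap4, siWiz, siZic2 and siNeg) held 2 libraries, described as biological duplicates in the series design. Library totals were 8326675 and 8829051 counted reads in siTfap4, 11200948 and 10544436 in siWiz, 13788856 and 9328709 in siZic2, and 11395211 and 10795092 in siNeg. Of the 55421 genes counted, 14647 passed the expression filter and were tested. All adjusted p-values for genes came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over these genes, unless another method is named.

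The targeted transcripts were examined first in every library. Tfap4 (Ensembl ENSMUSG00000005718; GRCm38 chromosome 16, 4544661 to 4559854, minus strand) had 97 and 134 counts in siTfap4 against 402 and 386 in siNeg. Its level was 13.9 ± 2.60 CPM (SD, n = 2) in siTfap4 and 35.3 ± 2.60 CPM in siNeg, or 39.4% of the control (95% confidence interval 27.1 to 57.2%; log2 fold change -1.34, SE 0.25, adjusted p = 0.00417). Tfap4 held 30.8 ± 3.06 CPM in siWiz and 32.0 ± 1.45 CPM in siZic2. Wiz (ENSMUSG00000024050; chromosome 17, 32354055 to 32389439, minus strand) had 188 and 206 counts in siWiz against 600 and 480 in siNeg, a level of 18.2 ± 2.06 against 48.0 ± 2.65 CPM. It stood at 38.0% of the control (interval 26.5 to 54.3%; log2 -1.40, SE 0.24). That was the smallest p-value of the siWiz comparison, 4.83e-05, yet the adjusted p over all genes was 0.708, and adjusted over the 3 targeted genes alone it was 0.000145. DESeq2 gave Wiz an adjusted p of 0.00315. Zic2 (ENSMUSG00000061524; chromosome 14, 122475435 to 122479852, plus strand) was a low transcript, with 31 and 17 counts in siZic2 against 54 and 23 in siNeg (1.99 ± 0.226 against 3.35 ± 1.61 CPM). Its 59.5% of the control had an interval of 30.3 to 117% and did not pass the test (log2 -0.75, SE 0.45, adjusted p = 1 over all genes and 0.120 over the 3 targeted genes). The Zic2 difference rested on the controls: its log2 fold change was -0.11 without siNeg replicate 1 and -1.16 without siNeg replicate 2. In siTfap4, Wiz held 33.0 ± 4.06 CPM (log2 -0.54, adjusted p = 0.131; log2 -1.14, adjusted p = 0.00747 after a correction for GC content and length) and Zic2 held 5.80 ± 0.570 CPM (log2 0.78, adjusted p = 0.230; log2 1.40 without siNeg replicate 1). Adjusted over the 3 targeted genes alone, each in its own siPOOL, Tfap4 had a p of 0.000159.

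**Figure D1:**
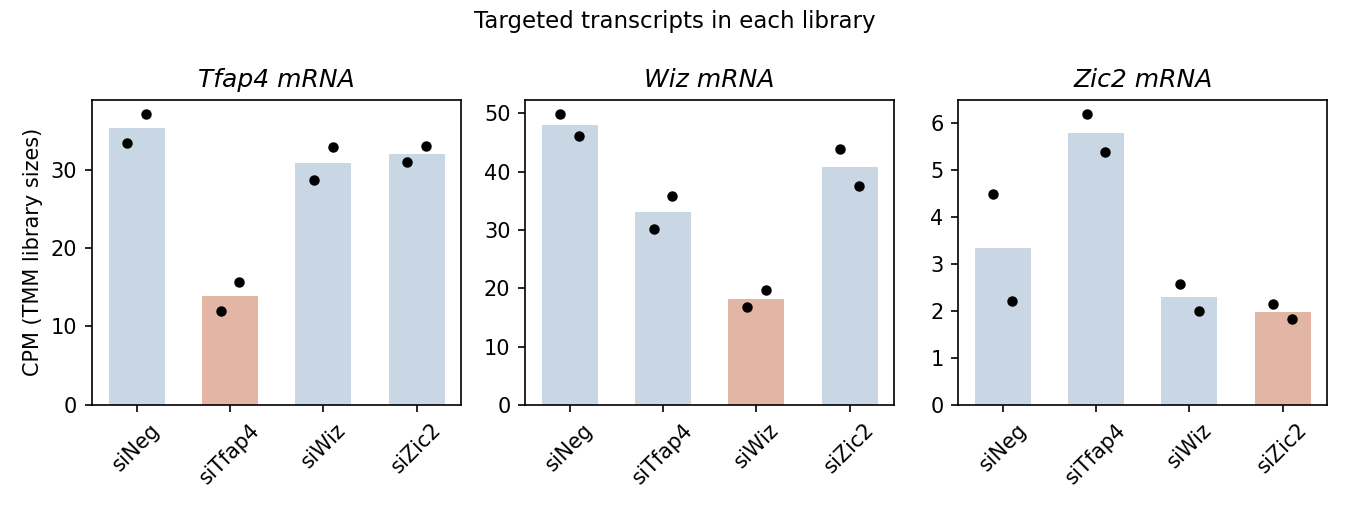
Level of Tfap4, Wiz and Zic2 mRNA in CPM on TMM library sizes (y axis, 1 panel per gene) in the 4 groups (x axis); bars are means of 2 libraries, points are single libraries, and red bars mark the group whose siPOOL targets that gene. Tfap4 averaged 13.9 CPM in siTfap4 against 35.3 in siNeg and Wiz 18.2 CPM in siWiz against 48.0, while the siNeg libraries spread around 3.35 CPM for Zic2, with 1.99 in siZic2.

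The comparison of siTfap4 with siNeg asked which transcripts differ when Tfap4 is lowered in cells without the microRNA cluster. Large losses with small p-values were in Dppa5a, an RNA-binding protein of pluripotent cells, and in Txnip, an inhibitor of thioredoxin. Dppa5a fell from 432 ± 80.4 to 6.49 ± 3.92 CPM (66.3-fold lower; log2 -6.05, SE 0.58, adjusted p = 0.000365). Txnip fell from 316 ± 55.9 to 10.7 ± 3.07 CPM (29.4-fold lower; log2 -4.88, SE 0.39, adjusted p = 9.44e-05). The polyubiquitin gene Ubb was 35.2-fold lower, the chromatin gene Morf4l2 9.95-fold lower and Dnmbp, an activator of the GTPase Cdc42, 6.83-fold lower. Dppa5a and Ubb share most of the sequence at their transcript ends with other genes, so their counts are uncertain. Gains were smaller: Serpine2, a secreted serine protease inhibitor, rose 3.31-fold and the actin-severing protein gene Dstn 3.03-fold. In all, 621 genes rose and 1709 fell (2330 of 14647; 4745 had an unadjusted p under 0.05). The median called gene was 2.02-fold higher or 2.89-fold lower, and 538 genes fell at least 4-fold against 24 that rose as much. Of the called genes 73.3% were lower. Among protein-coding genes 68.2% were lower, and 62.8% after a correction for GC content and length, both chosen after seeing the data.

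Further large losses by the naming rule were in Pfn1, which binds actin monomers (log2 -5.57), Ctnnd1, the cadherin-binding p120 catenin (-5.40), Pmpcb, a subunit of the mitochondrial processing peptidase (-5.23), and Fbxl14, a substrate receptor of a ubiquitin ligase (-5.10). The processed pseudogene Gm20305 had 0 counts in siTfap4 against 153 in siNeg, at least 37.7-fold lower at a floor of 3 counts over the group. Ccng2, an atypical cyclin, had 2 counts in siTfap4 against 236, or 1.15% of the control (counting interval 0.138 to 4.18%). The remaining large gains were Snord89, a small nucleolar RNA gene inside the gene model Gm15832 (log2 2.02), Pkp3, a desmosomal plakophilin (1.69), Gyg, which primes glycogen synthesis (1.62), Clybl, a mitochondrial enzyme (1.58), and 2 processed pseudogenes. Pfn1, Ctnnd1, Pmpcb and Fbxl14 kept their calls with any 1 library left out, but without siNeg replicate 1 their log2 changes shrank to -4.19, -4.23, -3.78 and -4.24. Without siNeg replicate 2 those of Pfn1, Ctnnd1 and Pmpcb were -6.27, -6.04 and -5.94, and Dppa5a stood at -6.87 and Pmpcb at -6.08 without siTfap4 replicate 2. Ccng2 also moved, to -9.81 without siTfap4 replicate 1, -5.31 without siTfap4 replicate 2 and -5.33 without siNeg replicate 1, values that depend on its near-zero counts. Without siTfap4 replicate 1, Pkp3 had an adjusted p of 0.0811 and Clybl of 0.0501, and without siNeg replicate 1 Pkp3 had 0.0641. For Gyg the adjusted p was 0.0711 without siTfap4 replicate 1, 0.0848 without siTfap4 replicate 2 and 0.189 without siNeg replicate 1.

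Pluripotency genes moved in both directions in siTfap4. Of 20 tested naive pluripotency factors, 5 fell and 15 did not pass the test, and adjusted over the list alone 6 fell. Besides Dppa5a these were Nr0b1, an orphan nuclear receptor (25.9-fold lower), the homeobox factor Nanog (-1.48, SE 0.35, adjusted p = 0.0142), the homeobox factor Gbx2 (-1.37) and Spp1, the secreted glycoprotein osteopontin (-1.19, adjusted p = 0.0167), which is named after its values were seen. The sixth over the list alone was Klf2 (-0.73, adjusted p = 0.0509 over all genes and 0.0272 over the list alone). Of 13 general pluripotency factors 3 rose and 10 did not pass, and 4 rose adjusted over the list alone. These were the POU factor Pou5f1 (1.02, SE 0.25, adjusted p = 0.0159), the RNA-binding protein gene Lin28a (0.81) and Dppa4 (0.78). Neither list stood apart from the other genes in camera (adjusted p = 0.0531 for naive and 0.157 for general factors). Of 14 formative and primed markers 1 fell, Fgf15 (log2 -1.30), and 0 adjusted over the list alone by edgeR, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.988). DESeq2 called 1 of them higher and 1 lower over all genes. Of 6 tested markers of the 2C-like state, which resembles the early embryo, edgeR called 0 over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05, and DESeq2 called 0 (camera adjusted p = 0.988). Except for Dppa5a and Nr0b1, these pluripotency calls were lost when single libraries were left out: without siTfap4 replicate 1 the adjusted p was 0.111 for Nanog, 0.0510 for Gbx2, 0.149 for Spp1, 0.108 for Pou5f1, 0.216 for Lin28a and 0.244 for Dppa4, and without siNeg replicate 1 it was 0.0846 for Nanog, 0.122 for Spp1, 0.0990 for Pou5f1, 0.119 for Lin28a and 0.166 for Dppa4. Without siNeg replicate 2 it was 0.0930 for Lin28a and 0.0756 for Dppa4, without siZic2 replicates 1 and 2 it was 0.0583 and 0.0584 for Lin28a and 0.0701 and 0.0692 for Dppa4, and without siWiz replicate 2 it was 0.0551 for Dppa4. The adjusted p of Fgf15 was 0.251 without siTfap4 replicate 1, 0.0667 and 0.0648 without siZic2 replicates 1 and 2, and 0.189 and 0.0518 without siNeg replicates 1 and 2. With the siTfap4 and siNeg libraries alone the adjusted p was 0.0918 for Lin28a, 0.122 for Dppa4 and 0.0748 for Fgf15, and with library totals alone it was 0.0503 for Dppa4. Without siTfap4 replicate 2 the log2 change of Nanog was -2.21. Nr0b1 kept its call with any 1 library left out, with log2 changes of -4.04 and -6.02 without siTfap4 replicates 1 and 2, and -3.46 and -5.36 without siNeg replicates 1 and 2.

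Wnt target genes were lower in siTfap4 as a list by camera with its preset correlation (adjusted p = 0.00373). That call was lost with an estimated correlation (adjusted p = 0.711), with fry (adjusted p = 0.0629) and without siTfap4 replicate 2 (adjusted p = 0.0591). Of 11 tested, 5 fell and 6 did not pass the test, over all genes and adjusted over the list alone, with a median log2 change of -1.28. They were Tcf7, a transcription factor of the pathway (log2 -3.57, SE 0.39, adjusted p = 0.000415), the secreted Wnt inhibitor Notum (-4.24, SE 0.72), the cell cycle activator Ccnd1 (-1.28, SE 0.23, adjusted p = 0.00339), the ubiquitin ligase gene Znrf3 (-1.50) and the homeobox factor Cdx1 (-2.19). Without siTfap4 replicate 1 the adjusted p was 0.0609 for Znrf3 and 0.149 for Cdx1, and without siNeg replicate 1 it was 0.0889 for Cdx1. Notum kept its call, but its log2 change was -2.63 without siNeg replicate 1, -4.98 without siNeg replicate 2, and -3.60 and -5.49 without siTfap4 replicates 1 and 2.

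Other signalling targets gave mixed results. Of 16 ERK target genes 5 fell and 1 rose (5 and 2 adjusted over the list alone; camera adjusted p = 0.271). They included the ERK phosphatase gene Dusp6 (log2 -3.55, SE 0.41, adjusted p = 0.000415) and the immediate early gene Ier2 (-1.16, SE 0.22). Of 14 LIF and STAT3 targets 3 fell (3 lower and 1 higher adjusted over the list alone; adjusted p = 0.593), with Socs3, the feedback inhibitor of STAT3, at -3.46 (SE 0.52). Of 13 Nodal and BMP targets 3 fell (4 over the list alone; adjusted p = 0.345), among them the BMP pseudoreceptor gene Bambi (-4.85) and Id3, an inhibitor of helix-loop-helix factors (-2.15). Of 16 relatives and partners of the targeted factors 4 fell and 1 rose (the same numbers adjusted over the list alone; adjusted p = 0.537), and those that fell included the Hedgehog pathway genes Gli2 (-2.34) and Ptch1 (-1.43). Dusp6, Socs3, Bambi, Id3 and Gli2 kept their calls but moved: without siTfap4 replicate 2 Dusp6 was at -4.53, Socs3 at -5.00, Id3 at -3.42 and Gli2 at -3.10, without siTfap4 replicate 1 Socs3 was at -2.75 and Id3 at -1.50, and without siNeg replicate 1 Bambi was at -4.15.

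Genes of DNA replication and mitosis fell more often than they rose, as did the called genes as a whole (73.3% lower), and without a list call. Of 27 replication genes 9 fell and 2 rose (10 and 5 adjusted over the list alone; camera adjusted p = 0.220), and of 25 mitosis genes 9 fell and 1 rose (10 and 1; adjusted p = 0.0800). The helicase subunit genes Mcm4 (log2 -2.49, SE 0.40) and Mcm6 (-1.42), the ribonucleotide reductase gene Rrm2 (-1.95) and the flap endonuclease gene Fen1 (3.96-fold lower) were among the replication genes. The mitotic kinase gene Cdk1 fell from 195 ± 61.3 to 30.3 ± 23.9 CPM (log2 -2.68, SE 0.44, adjusted p = 0.00195), and the checkpoint kinase gene Bub1b fell 2.96-fold. Ribosomal protein genes were called lower as a list (10 fell, 1 rose and 19 did not pass of 30, 12 fell and 4 rose adjusted over the list alone; median log2 -0.54, range -3.42 to 1.00; camera adjusted p = 0.0206). That list call was lost with an estimated correlation (adjusted p = 0.977), with fry (0.621), without siTfap4 replicate 1 (0.0940), without siNeg replicate 2 (0.375) and with a minimum mean of 5 CPM (0.0560). Of the 30 members, 14 share most of the sequence at their transcript end with other genes, so their counts are uncertain. Rps23 fell from 576 ± 158 to 60.7 ± 7.31 CPM (9.48-fold lower), and Rpl15 and Rpl11 were at -3.07 and -3.01. Of 25 ribosome biogenesis genes 3 fell and 1 rose, the same over the list alone (adjusted p = 0.648), with Gar1, a protein of small nucleolar particles, at -3.17. The calls of Mcm4, Mcm6, Rrm2, Fen1, Cdk1, Bub1b, Rps23, Rpl15, Rpl11 and Gar1 held with any 1 library left out, though without siTfap4 replicate 2 Cdk1 was at -3.87, Rrm2 at -2.68, Gar1 at -4.30, Rpl11 at -4.14 and Rpl15 at -3.97, and without siTfap4 replicate 1 Cdk1 was at -2.05, Gar1 at -2.56 and Rpl11 at -2.39.

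Among lineage and adhesion genes, 4 of 14 EMT genes (epithelial to mesenchymal transition) fell, the same over the list alone (camera adjusted p = 0.215), led by the intermediate filament gene Vim, from 282 ± 31.8 to 94.0 ± 1.41 CPM (log2 -1.59, SE 0.24, adjusted p = 0.00146). Epithelial genes went both ways (3 fell and 2 rose of 17, 4 and 2 over the list alone; adjusted p = 0.823). Of 13 trophectoderm markers 3 fell, also over the list alone (adjusted p = 0.648), and of 16 primitive endoderm markers 2 fell, with 0 adjusted over the list alone by edgeR, 6 at an unadjusted p under 0.05 and 1 called by DESeq2 over all genes (camera adjusted p = 0.994). Of 11 neural markers 1 fell, Sox21 (log2 -1.41), also over the list alone (adjusted p = 0.842). Of 7 mesoderm markers edgeR called 0, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.823), and of 6 fibroblast markers 0, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.994). Both counts were also 0 adjusted over the list alone and by DESeq2. Camera's direction was higher for the primitive endoderm list (median log2 0.04, mean -0.47) and for the fibroblast list (median -0.01, mean -0.27), against the sign of these means. The adjusted p of Sox21 was 0.203 without siTfap4 replicate 1 and 0.202 without siNeg replicate 1, and its log2 change was -2.04 without siTfap4 replicate 2.

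Stress-related lists were split. Of 28 integrated stress response genes 6 rose and 4 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.958, direction higher, with a median log2 of 0.22 and a mean of -0.09), including Ddit3, which encodes the transcription factor CHOP (log2 1.34, SE 0.30), and Phgdh, the first enzyme of serine synthesis (-2.61, SE 0.35). Of 25 p53 target genes 3 rose and 1 fell, the same over the list alone (adjusted p = 0.751), and the cyclin-dependent kinase inhibitor gene Cdkn1a, at once a described target of the deleted microRNAs, rose from 147 ± 10.5 to 300 ± 24.5 CPM (log2 1.02, SE 0.24). Of 12 described targets of the deleted microRNAs 3 fell and 1 rose, the same over the list alone (adjusted p = 0.917, direction lower, with a median log2 of 0.09 and a mean of -0.23). Of 19 interferon-stimulated genes 1 rose and 1 fell, also over the list alone (adjusted p = 0.648). Phgdh held in every fit with 1 library left out. The adjusted p of Ddit3 was 0.137 without siTfap4 replicate 1 and 0.0516 without siNeg replicate 1, and that of Cdkn1a 0.0524 without siNeg replicate 2.

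On the first principal component the siTfap4 libraries stood apart from the other 6 and from each other. This component, 59.8% of the variance, placed them at -103 and -57.7 and the other libraries between 1.85 and 38.9. In log2 CPM, siTfap4 replicate 2 correlated at 0.964 with siTfap4 replicate 1, 0.962 with siWiz replicate 2 and 0.957 with siNeg replicate 2. For siTfap4 replicate 1 the correlations with libraries of other groups were 0.889 to 0.922. Among the 12479 protein-coding genes with a GC value, those called lower in siTfap4 had a median GC content of 39.0% over the last 300 bases of the transcript, against 50.3% for genes called higher and 42.7% for all of them. Without siTfap4 replicate 1 the comparison gave 6 higher and 498 lower genes, and without siNeg replicate 1 it gave 55 and 702. Of 98 named genes called in siTfap4 against siNeg, 42 kept their call with any 1 library left out, 54 lost it without siTfap4 replicate 1, 42 without siNeg replicate 1, 19 without siNeg replicate 2 and 8 without siTfap4 replicate 2. More of these calls were lost without either siZic2 library, which is not in this comparison, than without siTfap4 replicate 2. Of the 97 named genes other than Tfap4, 63 lost their call with a covariate for the difference between the 2 siWiz libraries in the fit of all 8 libraries, as did Spp1 (adjusted p = 0.247). Of the 93 with a GC value, 11 lost it after the GC and length correction, among them Ddit3 (0.0645) and Sgce (0.0643). Most of the sequence at the transcript end is shared with other genes for Dppa5a (53.3% of its words of 36 bases), Ubb (72.8%) and Rpl10 (100%), so their counts are uncertain. The ends of Ccnd1, Ddit3, Fen1, Pou5f1, Sox4 and Tpi1 overlap exons on the opposite strand. Txnip lies within the gene model Gm15441, Fbxl14 within Wnt5b, Gm20305 within Sde2, and Mvd and Slc7a5 within Gm20388, while the use of strand in counting is not given in the sources used here.

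**Figure D2:**
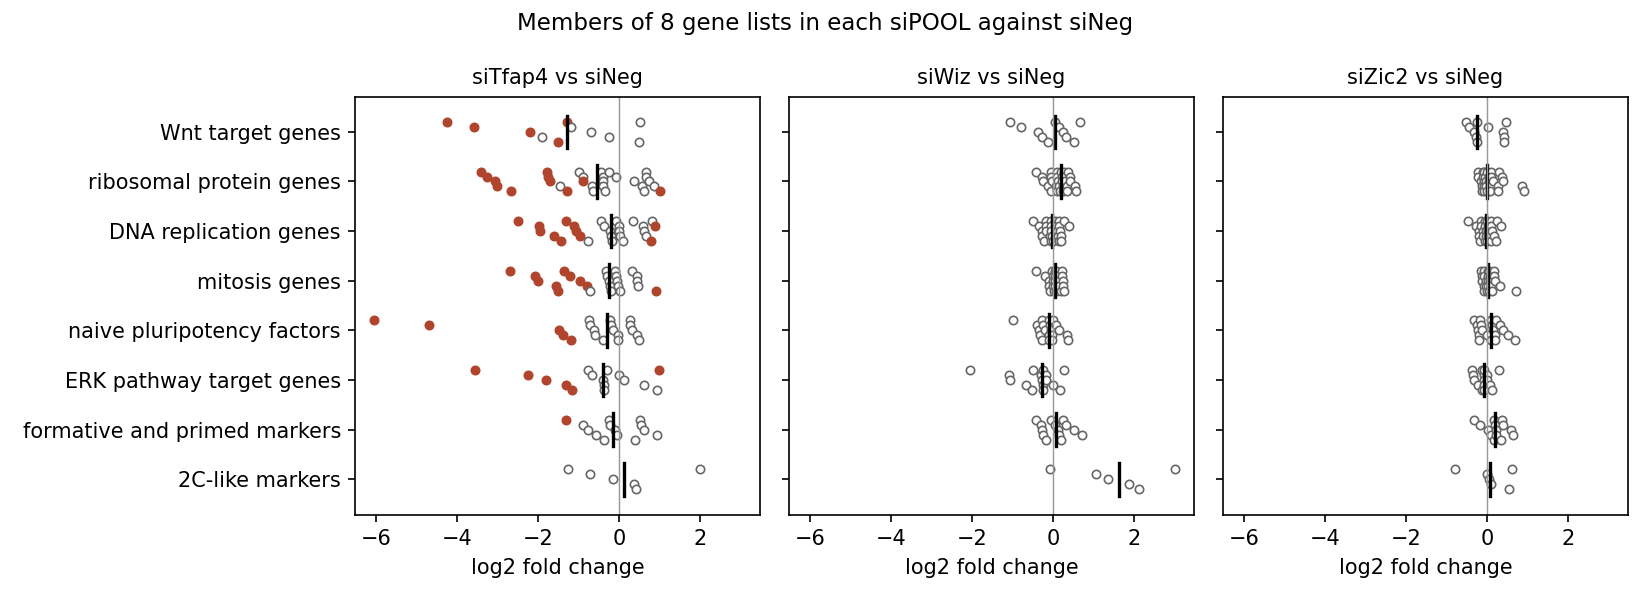
Log2 fold change (x axis) of each tested member of 8 gene lists (y axis) in siTfap4, siWiz and siZic2 against siNeg (1 panel each); each point is a gene, filled points passed an adjusted p of 0.05 in edgeR's test, and vertical bars are list medians. Filled points occur for siTfap4 alone, with Wnt target genes at a median of -1.28, and the 2C-like markers have a median of 1.62 in siWiz with no filled point.

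The comparison of siWiz with siNeg asked the same question for Wiz. Markers of the 2C-like state were higher as a list by camera with its preset correlation (adjusted p = 1.86e-05), and this call was lost with an estimated correlation (adjusted p = 0.868) and with fry (0.748). Usp17lc, a deubiquitinase gene of a multicopy family, was at 3.02 ± 0.733 CPM in siWiz and 0.371 ± 0.290 CPM in siNeg (log2 3.02, SE 0.77, adjusted p = 1 over all genes and 0.00972 adjusted over the list alone), and Zscan4a, annotated as an unprocessed pseudogene of a zinc finger family, was at a log2 difference of 2.13 (SE 0.95). Usp17lc was at 2.37 without siNeg replicate 1 and 4.08 without siNeg replicate 2, and Zscan4a at 1.34 without siWiz replicate 2. Of 6 tested members 5 had positive differences (median log2 1.62) and edgeR called 0 over all genes and 1 adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2. ERK target genes were lower as a list by camera with its preset correlation: 13 of 16 had negative differences (median log2 -0.26, camera adjusted p = 0.00373), and edgeR called 0 over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05 and 0 called by DESeq2. That list call was lost with an estimated correlation (adjusted p = 0.711), with fry (0.438), without siWiz replicate 2 (0.0671) and without siNeg replicate 1 (0.364). The growth regulator Myc was at 1.59 ± 0.901 CPM against 6.57 ± 6.58 (log2 -2.04, SE 0.68, adjusted p = 0.156 over the list alone). That Myc difference was -0.25 without siNeg replicate 1, -2.80 without siNeg replicate 2 and -2.78 without siWiz replicate 1.

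No gene passed the test in siWiz by edgeR over all genes (0 of 14647, with 266 at an unadjusted p under 0.05); DESeq2 called 1, Wiz itself. Without a filter on low counts edgeR called 6 higher and 6 lower, and Wiz had an adjusted p of 0.0118, Usp17lc of 0.0345, Myc of 0.0282 and the matricellular protein gene Ccn2 of 0.0187 (log2 -1.73). Of the other 28 lists tested none was called, with camera adjusted p from 0.0800 for ribosomal protein genes upward (median log2 0.19, 22 of 30 positive). Among these, 1 list had a member that passed adjusted over the list alone, the fibroblast markers, through Loxl1, an enzyme that cross-links elastin and collagen (log2 1.83, SE 0.51, adjusted p = 0.0180 over the list alone, camera adjusted p = 0.988 with a list median of -0.19). Single genes of interest with values but no call included the imprinted growth inhibitor gene Cdkn1c (log2 0.64) and the amino acid transporter gene Slc7a5 (-1.07, SE 0.31). On simulated counts with the same depth and spread and 200 changed genes, the siWiz comparison recovered 70.3% of 4-fold, 13.7% of 2-fold and 2.99% of 1.5-fold changes, so 2-fold and smaller changes were mostly not detectable. With fewer changed genes the adjustment is stricter, so these shares may be too high for the real comparison. Wiz, at an unadjusted p of 4.83e-05 in edgeR's test, had an adjusted p of 0.708.

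The comparison of siZic2 with siNeg asked the same for Zic2. Formative and primed markers, genes that mark the step from naive to primed pluripotency, were higher as a list by camera with its preset correlation (adjusted p = 0.0260). The call was lost with an estimated correlation (adjusted p = 0.868), with fry (0.772), without siZic2 replicate 1 (0.750), without siNeg replicate 2 (0.792) and without a filter on low counts (0.0768). Of 14 tested, 12 had positive differences (median log2 0.21) and edgeR called 0 over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05 and 0 called by DESeq2. Zic5, a relative of Zic2, was at 47.3 ± 9.97 CPM against 30.1 ± 6.69 (log2 0.65, SE 0.29, adjusted p = 0.463 over the list alone) and the SOX factor gene Sox4 at 13.9 ± 1.81 against 9.19 ± 2.53 (log2 0.59). No gene was called by edgeR (0 of 14647, with 86 at an unadjusted p under 0.05) or by DESeq2 (0). The other 29 lists were not called; the nearest were ribosome biogenesis genes, 2 of 25 positive (median log2 -0.13, camera adjusted p = 0.0531), and no member of any list passed adjusted over the list alone. On simulated counts with 200 changed genes, 75.8% of 4-fold and 17.9% of 2-fold changes were recovered, shares that may be too high where few genes change. Since Zic2 itself did not pass the test, the group is siZic2 by its label.

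The siPOOL groups were also set against each other, which leaves the control libraries out of the difference. Against siWiz, siTfap4 had 682 genes higher and 1525 lower, and against siZic2 1232 higher and 2147 lower. Morf4l2, Txnip, Dppa5a and Ubb were among the 5 genes with the smallest p by the naming rule in both: Txnip was at log2 -4.55 (SE 0.38, adjusted p = 9.52e-05) against siWiz and -5.08 (SE 0.39, adjusted p = 4.75e-05) against siZic2. Hax1, an antiapoptotic mitochondrial protein gene, was 22.7-fold lower against siWiz, with 51.1% of its end shared with other genes, and Dnmbp 8.91-fold lower against siZic2. The shared part was larger for Dppa5a (53.3%) and Ubb (72.8%), so the counts of Hax1, Dppa5a and Ubb are uncertain. Tfap4 fell in both (log2 -1.15, adjusted p = 0.0104, and -1.20, adjusted p = 0.00545). Zic2 was higher in siTfap4 than in siZic2 (log2 1.53, SE 0.45, adjusted p = 0.0275) and Wiz higher than in siWiz (0.86, adjusted p = 0.0304). Zic2 held 2.30 ± 0.411 CPM in siWiz against 1.99 ± 0.226 CPM in siZic2 (log2 0.20, SE 0.465). Between siTfap4 and siWiz the Zic2 difference was log2 1.33 (adjusted p = 0.0601). The Zic2 call against siZic2 therefore does not show a lowering particular to siZic2. In the same direction in all 3 comparisons of siTfap4, 369 genes were higher and 1280 lower, and the 5 with the smallest largest p were Morf4l2, Txnip, Dppa5a, Ubb and Dnmbp, a use of the naming rule decided after the data were seen. These 3 comparisons share the same siTfap4 libraries, so they are not independent, and a trait of those libraries alone would give the same call in each. Between siWiz and siZic2 edgeR called no gene (0, with 384 at an unadjusted p under 0.05), and DESeq2 called 0.

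The counts of siTfap4 against siWiz moved to 401 without siTfap4 replicate 1 and 407 without siWiz replicate 1, and to 1411 with these 4 libraries alone. Against siZic2 they were 905 without siTfap4 replicate 1, 1288 without siZic2 replicate 1 and 1264 without siZic2 replicate 2. Morf4l2, Txnip, Dppa5a, Ubb, Hax1 and Dnmbp kept their calls with any 1 library left out. Against siWiz, without siWiz replicate 1, the log2 changes were -5.23 for Dppa5a, -4.59 for Ubb, -3.77 for Hax1 and -3.89 for Txnip, and without siWiz replicate 2 they were -7.03 for Dppa5a and -6.21 for Ubb. Without siTfap4 replicate 2 Dppa5a was at -7.21 against siWiz and -7.55 against siZic2. Tfap4 lost its call without siTfap4 replicate 1 (adjusted p = 0.0946 and 0.0514). The Wiz difference had an adjusted p of 0.0727 and 0.0742 without siTfap4 replicates 1 and 2, 0.239 and 0.0695 without siWiz replicates 1 and 2, 0.0587 and 0.0584 without siZic2 replicates 1 and 2, and 0.0730 with the siTfap4 and siWiz libraries alone. After the GC and length correction it was at log2 0.30 (adjusted p = 0.408). With the siWiz covariate and all 8 libraries the adjusted p was 0.124 for this difference, 0.0511 for Tfap4 and 0.107 for Zic2 against siZic2. The Zic2 difference had 0.136 without siTfap4 replicate 1, and 0.131 and 0.154 without siZic2 replicates 1 and 2.

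The 3 comparisons with siNeg share the 2 control libraries, so their correlations were set against unchanged groups simulated against the same controls. Since edgeR called 0 genes in siWiz and 0 in siZic2, the overlap of calls between siPOOLs could only be 0 and was not tested. Across genes, which are not independent replicates, the log2 fold changes of siWiz and siZic2 correlated at r = 0.316 (simulated 0.501; covariance 0.0382, simulated 0.0827). Those of siTfap4 and siWiz correlated at 0.263 (simulated 0.488; covariance 0.0876, simulated 0.0826), and those of siTfap4 and siZic2 at -0.131 (simulated 0.490; covariance -0.0369, simulated 0.0828). Each correlation lay below its simulated value. The covariance of siTfap4 and siWiz lay slightly above its simulated value. The covariances with siZic2 lay well below theirs, so the simulation may overstate the part of the controls. It therefore cannot tell whether the shared controls alone account for the positive correlations. The simulation took 1 estimate of spread per gene for all groups and may misstate that of the controls. A fit with a separate control library for each comparison was not run.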

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

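The siTfap4 and siWiz library omissions as groups, the covariate for the difference between the 2 siWiz libraries, the protein-coding subset, the GC and length correction and the thinning were tests chosen after seeing the data. With any 1 library left out, the siTfap4 comparison with siNeg (2330 genes) gave 504 (without siTfap4 replicate 1; 757 without siNeg replicate 1) to 3322, that with siWiz (2207) 401 (without siTfap4 replicate 1; 407 without siWiz replicate 1) to 3279, and that with siZic2 (3379) 905 (without siTfap4 replicate 1; 1288 and 1264 without siZic2 replicates 1 and 2) to 4057. The other 3 comparisons gave 0 to 0. The lists called went from 1 (without siTfap4 replicate 1) to 3 in siTfap4 (2), 2 to 3 in siWiz (2) and 1 to 3 in siZic2 (1; 3 without siZic2 replicate 2, and 2 without siTfap4 replicate 2, siZic2 replicate 1 or either siNeg library). In the same omissions the log2 change of Tfap4 in siTfap4 went from -1.56 to -1.17, that of Wiz in siWiz from -1.52 to -1.28 and that of Zic2 in siZic2 from -1.16 to -0.11. Each omission left the same number of libraries in the fit, so that number alone cannot explain the range between omissions. In all 3 siTfap4 comparisons the fewest calls came without siTfap4 replicate 1 and the most without siTfap4 replicate 2. The cause was not tested. Without a filter on low counts edgeR tested 26969 genes and called 12 in siWiz against siNeg, 23 in siWiz against siZic2, an overlap of 4 genes between siPOOLs, and 4, 2 and 0 lists in siTfap4, siWiz and siZic2. With a mean of at least 5 CPM it called 1 list in siTfap4 and 3 in siZic2, the 2C-like list had too few members to test and Zic2 had no value. With the compared groups alone, siTfap4 against siWiz gave 1411 genes, and 4 lists were called in siTfap4 and 3 in siZic2. Neither camera with an estimated correlation nor fry called a list (0 in siTfap4, 0 in siWiz and 0 in siZic2). DESeq2 called 1 gene in siWiz against siNeg. The replicate numbers were not taken as pairs, since the deviations of same-numbered libraries correlated at -0.043 between siTfap4 and siWiz, though at 0.134 to 0.332 in the other 5 of 6 pairs of groups, and replicate 1 lay above replicate 2 on the second principal component in all 4 groups. With the replicate number as a block the siTfap4 comparisons gave 3243, 3056 and 4391 genes, siWiz and siZic2 against siNeg 0, and siZic2 2 lists. With the siTfap4 libraries left out 2 lists were called in siZic2, and with the block added 3, and siWiz had 2 genes, Wiz lower and Gm21761 higher. With the siWiz libraries left out and the covariate, siTfap4 had 0 genes against siNeg and 0 against siZic2, and Tfap4 was at -1.56 (adjusted p = 0.698), in a fit that recovered 4.15% of 4-fold changes in a simulation. With the covariate and all 8 libraries it had 328 against siNeg, 605 against siWiz and 308 against siZic2, and siZic2 had 0 lists. siZic2 had 2 lists among protein-coding genes and 0 after the GC and length correction. Wiz in siWiz passed without a filter (log2 -1.40, adjusted p = 0.0118), with DESeq2 (-1.40, 0.00315), and with the siTfap4 libraries left out and a block (-1.41, 0.0389), against 0.708 in the report and up to 1 over its other alternatives. The direction turned for the 2C-like list in siZic2 without siZic2 replicate 2 (lower, adjusted p = 0.0211, with up to 0.932 when any 1 library was left out), and, in siTfap4 with the covariate and the siWiz libraries left out, for Gyg (-0.305), Sgce (1.64), Lrp2 (0.16), Spred2 (0.806), Dcxr (-0.04) and Bub1 (0.24). For the list counts, the DESeq2 call and the reversed directions the cause was not tested. The siTfap4 count against siNeg stayed within 1.5-fold with RLE factors (2338), library totals (2213, with 80.5% lower against 73.3%), a mean of 5 CPM (2245), the compared groups alone (1699), no filter (2950), DESeq2 (2737), GC and length corrected (2585) and thinned (2316) libraries, and was 2330 with a 1.5-fold minimum. The split moved more: 266 were higher and 1433 lower with the compared groups alone, and 1147 and 2096 with the replicate block, against 621 and 1709 in the report. Of 5254 values under the alternatives fixed in advance, 4825 kept direction and side of the threshold, 207 no longer passed, 46 newly passed, 175 moved and 1 reversed, and of 2227 under those added later, 1952, 188, 15, 66 and 6. With this depth, this spread, 2 libraries per group and 200 changed genes together, the simulations recovered 17.0%, 13.7% and 17.9% of 2-fold changes in siTfap4, siWiz and siZic2. The part of depth alone in this was not tested.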

Other observations

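The association tests with differences between libraries, the covariate fits and the tests of summed gene families were chosen after the results they concern were seen; the GC correction and the thinning had their bounds written before, but the form of the GC correction was revised after its first result. In siTfap4 against siNeg, metabolic genes went both ways. Slc2a1, a glucose transporter gene, fell (log2 -1.30, SE 0.25, adjusted p = 0.00455), as did the histone demethylase gene Kdm3a (-1.28) and the glycolytic enzyme gene Tpi1, while Pgam1, another glycolytic enzyme gene, rose (1.22). Of 24 glycolysis and hypoxia genes 3 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.994). Of 24 cholesterol synthesis genes 2 rose, the mevalonate pathway genes Mvd (1.30) and Pmvk (1.06), and 1 fell, also over the list alone (camera adjusted p = 0.648). Slc2a1 kept its call with any 1 library left out. Without siTfap4 replicate 1 the adjusted p was 0.101 for Tpi1, 0.175 for Pgam1, 0.0680 for Kdm3a, 0.0733 for Mvd and 0.152 for Pmvk. Without siNeg replicate 1 it was 0.0570 for Pgam1, 0.0784 for Kdm3a, 0.0678 for Mvd and 0.109 for Pmvk, and without siNeg replicate 2 it was 0.0796 for Pgam1.

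Single members fell in 4 further lists of siTfap4. Of all 14647 tested genes 1709 fell, so 1 lower member says little about its list. Xpo5, which exports microRNA precursors from the nucleus, fell (log2 -1.28, SE 0.24, adjusted p = 0.00459, kept with any 1 library left out), 1 of 14 genes of the RNA interference machinery and also over the list alone (camera adjusted p = 0.751). Hormad1, a meiotic chromosome protein gene, was the 1 of 17 germline genes that fell (-3.00, also over the list alone, camera adjusted p = 0.789; adjusted p = 0.0584 without siTfap4 replicate 1). Of 8 mitochondrially encoded mRNAs mt-Cytb fell (-1.56, also over the list alone, camera adjusted p = 0.958; adjusted p = 0.0970 without siTfap4 replicate 1, log2 -2.31 without siTfap4 replicate 2). Of 23 imprinted genes edgeR called 1, Sgce, lower (-2.33; camera adjusted p = 0.958 in the higher direction, with a list median of -0.04), and 0 over the list alone, with 6 at an unadjusted p under 0.05 and 2 called by DESeq2 over all genes. The adjusted p of Sgce was 0.271 and 0.0604 without siTfap4 replicates 1 and 2, 0.0571 and 0.0549 without siZic2 replicates 1 and 2, and 0.511 without siNeg replicate 1 (log2 -0.91), and its log2 change was -3.02 without siNeg replicate 2. Of the 22 genes of the protocadherin beta cluster 0 passed the expression filter, so that list was not tested. Loxl1, named above for siWiz, also had a log2 difference of 1.35 in siZic2 (unadjusted p = 0.0204) and 1.11 in siTfap4 (0.0568; 0.45 without siTfap4 replicate 2), all against the same siNeg level of 1.08 ± 0.237 CPM.

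More genes were called for siTfap4 than for the other siPOOLs, and GC content and length, or the lower depth of these libraries, are argued against as the whole cause: 2585 genes were called with GC content and length corrected (2380 of these genes before, 1859 in both), and 2316 with every library thinned to the smallest total. An axis along which libraries of other groups also differ is a candidate explanation, since over the called genes, which are not independent, the log2 change correlated with the difference between the 2 siWiz libraries at a Spearman rho of 0.674 (0.439 over all 14647 genes), though with that between the siZic2 libraries at -0.079 (-0.008), and that of siTfap4 against siZic2 with the difference between the siNeg libraries at 0.413 (0.255). With the score on that axis as a covariate and siWiz left out, the calls went from 2196 to 0, while the median log2 change, signed by the direction before, went from 1.38 to 1.03 with 90.1% of the genes keeping their sign, and the median SE from 0.321 to 0.740. The scores separate siTfap4 (0.465 and 0.416) from the others (-0.341 to 0). In a simulation this fit recovered 4.15% of real 4-fold changes against 79.8% without the covariate, so this loss of calls decides nothing. With the covariate in the fit of all 8 libraries, the calls went from 2330 to 328, of which 3 were higher and 325 lower. In a simulation that fit recovered 59.9% of 4-fold changes against 79.2% without the covariate. The median called gene changed less than 4-fold, so the simulation does not show how many of the lost calls were real, and the axis stays a candidate. The lowering of Tfap4 itself stays open, untested, beside that axis.

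The 2C-like markers were higher in siWiz than in siNeg as a list by camera with its preset correlation (adjusted p = 1.86e-05), but not with an estimated correlation (adjusted p = 0.868) or with fry (0.748). Reads placed on the wrong copy within a family are argued against as the source of the difference, since the counts summed over each family kept it. It was log2 1.72 for 6 Zscan4 genes (SE 0.78, unadjusted p = 0.0455, adjusted p = 1) and 1.94 for 4 Usp17l genes (SE 0.61, unadjusted p = 0.00710, adjusted p = 1). Most tested members were already higher, so positive sums add little. Shared reads may also let camera count 1 signal as several members. Camera was not run on the sums, so this stays open for the list call. Differences between cultures of 1 group stay open with 2 libraries per group, because the sum of both families differed between the siTfap4 libraries by 2.34 on the log2 scale, more than siWiz from siNeg (1.88), and between those of siNeg, siWiz and siZic2 by 1.30, 1.01 and 1.40. These differences had the same sign, with replicate 2 above replicate 1 in all 4 groups, and siWiz exceeded siNeg by 2.03 in replicate 1 (10.2 against 2.49 CPM) and 1.74 in replicate 2 (20.5 against 6.15 CPM), against -0.24 and 0.79 for siTfap4 (2.11 and 10.7 CPM) and -0.12 and -0.03 for siZic2 (2.29 and 6.02 CPM). The lowering of Wiz stays open as well, untested.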
